A study of Mus musculus with 24 samples.

How the data were processed

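Mouse testis germ cells carrying a knock-in allele of Ddx4, the gene of a DEAD-box RNA helicase of germ granules, were profiled in 24 libraries. Per the labels' protocols, round spermatid RNA libraries were made from 1 ug of total RNA with the NEBNext Ultra RNA kit, small RNA libraries from 200 ng of total RNA of enriched pachytene spermatocytes or round spermatids with the MGIEasy Small RNA kit, and CB RNA libraries from 25 ng of RNA with the strand-specific Hieff dual-mode kit, without selection of polyadenylated RNA and without removal of ribosomal RNA. CB is not spelled out in the labels, which give the cell type of these libraries only as germ cells. The genotypes were wild type, heterozygous knock-in and homozygous knock-in; no wild-type CB library was analysed here. The labels number the libraries of each group but do not say that they came from separate animals, so the p-values measure the spread between these samples, which may be technical.

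For the RNA libraries the authors deposited 1 table per library with expected counts, TPM and FPKM per Ensembl gene, per the file headers. The TPM and FPKM values deposited by the authors are normalised for gene length and library size and were used here only to check the units. The deposited expected counts, estimated reads that need not be whole numbers, were rounded to whole numbers. The column layout is that of RSEM, but the quantifier, the aligner and their versions are not given in the sources used here. Trim Galore and the build mm10 are named in the submitters' processing notes, without a version. For the small RNA libraries the authors deposited whole-number counts of reads per piRNA cluster, per the file headers; how reads matching several clusters were counted is not given in the sources used here. Library totals other than the reads on clusters were not used here, so every small RNA value is relative to cluster reads. Isoform tables were not used here.

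Gene tables held 55364 genes in the round spermatid files and 55401 in the CB files; the 37 genes listed in the CB files alone were all mitochondrially encoded. Symbols were found for all but 260 genes of either kind of file, and gene positions are those of the GRCm38.p6 annotation. The small RNA tables held 214 clusters, of which 5 were not listed in at least 1 library and were set to 0 there. All of these gaps were in the homozygous spermatid libraries, 4 in each, where the lowest listed counts were 86 and 68 reads. Other libraries listed clusters down to 15 reads, so a minimum for listing shared by all libraries would be at most 15 reads. Cluster names give a class, prepachytene (84), hybrid (30) or pachytene (100), and mm10 coordinates. Names beginning with pi- and a gene symbol were counted as genic (114) and names made of a chromosome band as intergenic (100). The groupings largely coincide, since 93 of the 100 pachytene clusters were intergenic and 81 of the 84 prepachytene clusters were genic. Intergenic clusters are named by chromosome and mm10 position.

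Total rounded counts were 15.3 to 24.9 M in the 6 round spermatid RNA libraries and 14.2 to 16.5 M in the 6 CB libraries. Cluster reads were 24.2 to 27.3 M in the 6 spermatocyte small RNA libraries and 9.23 to 24.1 M in the 6 spermatid libraries. A floor of 3 counts was used where a whole group had no count; such bounds cover counting error only, since reads without molecular identifiers are not independent molecules. A check for copied libraries found no pair of a group that matched within counting noise (chi-square over degrees of freedom at least 2.47 over genes or clusters with at least 20 counts). It cannot tell repeats of a sample from separate animals, and each library was treated as the replicate its label gives.

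Counts were tested with edgeR 4.0.16 (quasi-likelihood F test, TMM factors, filterByExpr by group) in R 4.3.3, with Benjamini-Hochberg adjustment and a threshold of 0.05; all adjusted p-values of single genes and clusters come from it unless DESeq2 is named. The 6 round spermatid RNA libraries were fitted together, the 6 CB libraries together, and the 12 small RNA libraries together, so that groups of 2 libraries shared an estimate of spread. The difference between the CB and round spermatid genotype effects, and between the spermatid and spermatocyte effects on clusters, was tested as an interaction contrast. CB and round spermatid levels themselves were not tested against each other, since kit and input differ with the kind of library. A difference between their genotype effects may also stem from kit, input or the cells used. Normalised levels are counts scaled to the TMM effective library size (CPM), given as mean ± SD. Cluster abundances are given as a percent of cluster reads. Because the scaling moved the median cluster, cluster changes are printed as log2 changes relative to the median cluster of the same comparison. The adjusted p-value beside such a change tests the fitted log2 change under TMM scaling. The change relative to the median cluster was itself not tested.

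Gene lists (19) covered the piRNA pathway, chromatoid body proteins, meiotic prophase, acrosome, chromatin compaction and late spermatids, flagellum, postmeiotic regulators, RNA decay, stress and apoptosis, ribosomal proteins, mitochondrially encoded genes, replication-dependent histones, small nuclear and nucleolar RNAs, and markers of spermatogonia, Sertoli, Leydig, peritubular and vascular, immune and erythroid cells. They were tested with camera (limma 3.58.1, preset correlation 0.01), again with an estimated correlation, and with fry; all list p-values were adjusted over the lists of a comparison, and lists needed at least 3 tested members. The tests, the lists, the alternative settings listed below except where stated, and the rule for naming genes were fixed before the data were examined. The rule took Ddx4, the 10 genes with the largest change in either direction among those past the threshold with a mean log2 CPM of at least 2, separate groups and a symbol that is not a predicted model or clone, up to 4 members of each list with a called member, the 3 genes of smallest p where nothing was called, the 5 clusters with the largest change in either direction with at least 100 reads on average, and the 5 clusters with most wild-type reads. A list of genes named in genic piRNA clusters was made after the data were seen, and its p-values were adjusted together with those of the fixed lists.

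Class medians of clusters were compared by a two-sided permutation of class labels (100000 permutations, 16 tests, Benjamini-Hochberg), and log2 changes of round spermatid and CB libraries by Pearson and Spearman correlation across genes with a permutation p; genes and clusters are not independent replicates. On counts simulated from the real means with 200 changed genes, edgeR recovered 14% of 2-fold and 79% of 4-fold changes for the homozygous against wild-type spermatid design over 17430 genes (6 false among 99 calls), 9% and 75% for the homozygous against heterozygous spermatid design over 17417 genes (7 of 91), and 67% and 98% for the CB design over 18899 genes (9 of 173). On 214 simulated clusters with 30 changed, it recovered 60% of 1.5-fold and 80% of 2-fold changes in the spermatocyte design, and 66.7% and 100% in the spermatid design. These simulations changed few features, about as many up as down, and gave every group the same spread. In the data most clusters were called and the spread differed between groups. The rates of recovery and of false calls need not carry over to the data. The class permutation, on clusters simulated with an SD of 0.6, estimated -0.17 for a simulated difference of 0 (p = 0.138) and 0.69 for 0.5 (p = 1e-05).

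The alternatives were DESeq2 1.42.0, size factors by RLE, total counts without TMM, no filter on low counts, a stricter filter (CPM of at least 5, or 100 reads per cluster), the replicate number as a block, only the compared libraries in the fit, CB counts without mitochondrial and small structural RNAs, and leaving out each library in turn. Added after the data were seen were a fit with a lowess trend of log2 on transcript length (span 0.3) removed per library, CB counts without the ribosomal RNA-like genes CT010467.1 and Lars2, list tests with the length trend removed or without wild-type round spermatid library 1 or heterozygous CB library 1, class tests with each library left out (10000 permutations), and a bootstrap of class medians over clusters (10000 draws). Lars2 is a protein-coding gene that was grouped as ribosomal RNA-like here, and whether its reads come from ribosomal RNA was not tested. Tables were handled with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and scipy 1.17.1, and plots drawn with matplotlib 3.10.9.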

Results

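RNA of round spermatids, the haploid cells that follow meiosis, was sequenced from wild-type, heterozygous and homozygous Ddx4 knock-in mice (n = 2 libraries each). CB RNA was sequenced from heterozygous and homozygous animals (n = 3 each). Small RNAs on piRNA clusters, the loci that give rise to PIWI-interacting RNAs, were counted in pachytene spermatocytes and round spermatids of all 3 genotypes (n = 2 each). Among the round spermatid RNA libraries, wild-type library 1 stood apart. Transcripts under 1000 bases took 19.3% of its counts against 11.6% in wild-type library 2 and 11.3% to 12.7% in the other four. Prm1 took 0.627% of its counts against 0.128% in wild-type library 2. The homozygous spermatid small RNA libraries were the shallowest of their kind, with 11.7 and 9.23 M cluster reads against 21.7 to 24.1 M in the other spermatid libraries.

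Ddx4 itself (ENSMUSG00000021758, chromosome 13, 112598333 to 112652633 in GRCm38.p6) was measured in every RNA library. In round spermatids its level was 482 ± 55.1 CPM in wild type, 405 ± 2.68 in heterozygotes and 125 ± 6.15 in homozygotes (SD, n = 2 each). It fell by 1.95 on the log2 scale in homozygotes against wild type (SE 0.124, adjusted p = 0.00543) and by 1.69 against heterozygotes (SE 0.123, adjusted p = 0.0138). The heterozygous difference from wild type, -0.25 (SE 0.12), did not pass the test (adjusted p = 0.519). In CB libraries Ddx4 stood at 284 ± 35.1 CPM in homozygotes and 318 ± 44.0 in heterozygotes (n = 3 each), a difference of -0.16 that did not pass the test (SE 0.133, adjusted p = 0.649). The genotype effect differed between the kinds of library by 1.59 on the log2 scale (SE 0.182, adjusted p = 0.0014 for the interaction). Kit, input and labelled cell type differ between them too, so the source of this difference cannot be told apart.

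**Figure D1:**
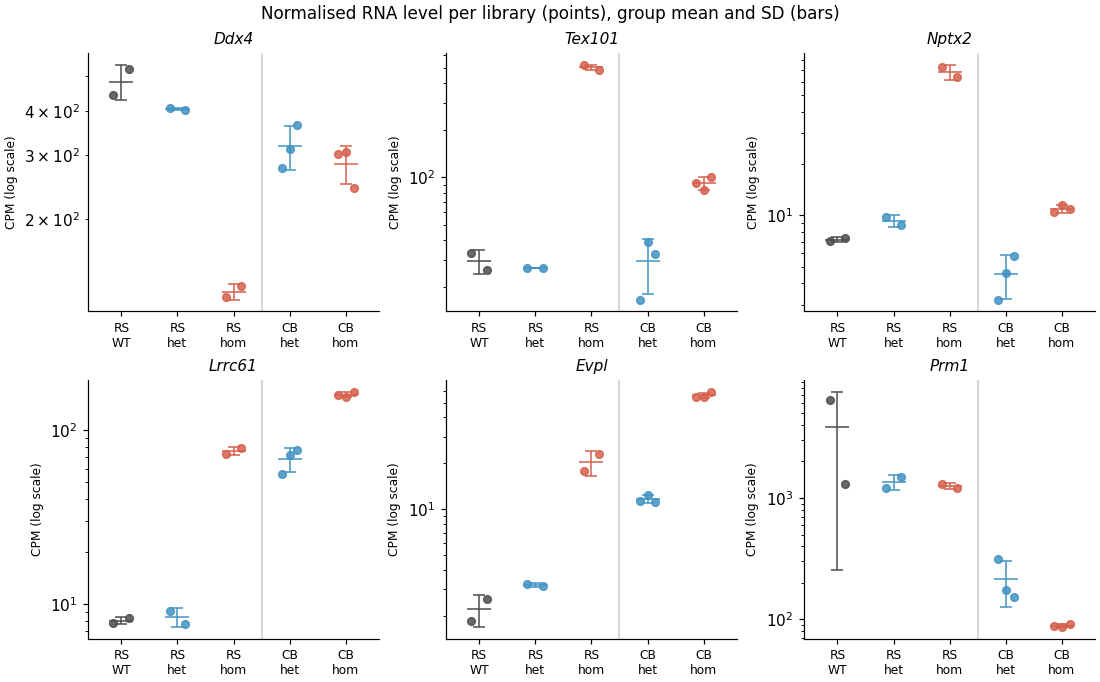
Normalised RNA level (CPM, log axis) of Ddx4, Tex101, Nptx2, Lrrc61, Evpl and Prm1 in each round spermatid (RS) and CB library (points), with group mean and SD (bars). Ddx4 lies at 121 and 130 CPM in the homozygous spermatid libraries and at 403 to 521 in the other four, while Tex101 lies at 502 CPM on average in the homozygous spermatids and under 34 in wild type and heterozygotes.

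The comparison of homozygous with wild-type round spermatids addresses what the knock-in does to the RNA of these cells. Tex101, which encodes a germ cell surface glycoprotein (chromosome 7, 24668012 to 24672050), rose from 29.5 ± 5.13 to 502 ± 21.0 CPM, a log2 change of 4.09 (SE 0.165, adjusted p = 0.00204). Angptl2, encoding a secreted angiopoietin-like protein, rose from 0.683 ± 0.0357 to 22.1 ± 0.938 CPM (log2 5.01, adjusted p = 0.00266). Nptx2, encoding neuronal pentraxin 2, rose from 7.22 ± 0.263 to 68.5 ± 6.89 CPM (log2 3.24, adjusted p = 0.00266). Sel1l3 (4.06), Psd4 (3.73), Tapbpl (3.60), Kif26b (3.42), the transcription factor gene Stat6 (3.35) and Wwc1 (3.24) also rose. Of each gene named here by the size of its change, every library of the group with the higher mean lay above every library of the other group. Fam205a2, a member of a multi-copy family whose reads may be split between copies, had 0 counts in wild type and 553 in homozygotes, at least 213-fold higher with a floor of 3 counts over the group. Idh1, encoding cytosolic isocitrate dehydrogenase, fell from 11.9 ± 3.16 to 2.83 ± 0.15 CPM (log2 -2.07, adjusted p = 0.0157). Also lower were Etfb, encoding a subunit of the electron transfer flavoprotein (-1.83, adjusted p = 0.0089), the zinc finger genes Zfp239 (-1.83) and Zfp72 (-1.69), Tbc1d22bos (-1.78), the V-ATPase subunit gene Atp6v1d (-1.63), Dact3 (-1.53), Ccdc117 (-1.51) and C1qtnf3 (-1.49).

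Of 17809 genes, edgeR called 510, 426 higher and 84 lower, with 4044 at an unadjusted p under 0.05. DESeq2 called 1287, 825 higher and 462 lower. The count moved with single libraries. EdgeR called 4927 genes (2478 higher, 2449 lower) without wild-type library 1 and 8488 (4553 and 3935) without wild-type library 2, where a lone wild-type library was taken to vary like the other groups. Without homozygous library 1 or 2 it called 0 genes (1932 and 1862 at an unadjusted p under 0.05; DESeq2 was not run on these subsets), and with only the compared libraries in the fit it called 15. It called 1386 higher and 1104 lower with the trend of log2 on transcript length removed, so the excess of higher calls depended on the setting.

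Of the piRNA pathway genes, 2 of 22 rose and 1, Ddx4, fell, with the same count adjusted over the list alone. Piwil2, encoding a PIWI protein, rose from 25.6 ± 5.71 to 59.9 ± 4.32 CPM (log2 1.23, adjusted p = 0.0312). Tdrd1, encoding a Tudor-domain protein, rose from 19.1 to 42.4 CPM (log2 1.15, adjusted p = 0.0337). The same 3 genes were the called members of the chromatoid body list (22 tested, also 3 adjusted over the list alone). Neither list was called as a whole (camera adjusted p = 0.63 and 0.201). The chromatoid body list was called lower without wild-type library 1 (adjusted p = 1.79e-05; 0.227 with an estimated correlation), with 15 of its 22 members called lower. Acrosome genes were lower as a list (camera adjusted p = 1.61e-06, adjusted p = 0.306 with an estimated correlation). Their median log2 change was -0.47. No member passed the test over all genes, and 12 of 23 were lower adjusted over the list alone. Without wild-type library 1 the median of acrosome genes was -0.319. The list of chromatin compaction and late spermatid genes was also called lower (median -0.30, camera adjusted p = 0.00582, adjusted p = 0.306 with an estimated correlation). Of its 23 members edgeR called 0, and 0 passed adjusted over the list alone. Without wild-type library 1 its median was -0.119. Replication-dependent histones were called lower (median -0.58, adjusted p = 0.00313, and adjusted p = 0.487 with an estimated correlation) with 0 of 18 members called either way. Ribosomal protein genes had a median of -0.46 and were called lower (adjusted p = 0.00582, and adjusted p = 0.808 with an estimated correlation), yet 2 of 85 rose. These were Rpl10a (2.63) and Rps3 (1.51), both with processed copies elsewhere in the genome that leave their counts uncertain. Without wild-type library 1 that list was called higher (adjusted p = 6.53e-05). The ribosomal protein (median -0.02, adjusted p = 0.782), late spermatid (-0.14, adjusted p = 0.211) and histone lists (-0.28, adjusted p = 0.0579) were not called with the length trend removed, and the acrosome list was (-0.38, adjusted p = 1.52e-05). No camera call of this comparison held with an estimated correlation, with all libraries or with the length trend removed (lowest adjusted p 0.305 and 0.154). None held without wild-type library 1 either, which left 1 wild-type library. By fry, immune markers (adjusted p = 0.00168), postmeiotic regulators (0.0247) and Sertoli markers (0.0431) passed. The acrosome (0.0612), late spermatid (0.0838), histone (0.177) and ribosomal protein lists (0.704) did not.

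Markers of other testicular cells went both ways. Immune markers were called higher (median 1.05, camera adjusted p = 5.12e-05, adjusted p = 0.305 with an estimated correlation), with 2 of 10 members called, Cd74 (from 2.81 to 9.32 CPM, log2 1.72) and Lyz2 (1.71), and 5 adjusted over the list alone. Sertoli markers were called lower (median -0.84, adjusted p = 0.00874, adjusted p = 0.306 with an estimated correlation), with Aard (-1.44) and Clu (-0.84) called of 14 and 3 adjusted over the list alone. Of the peritubular and vascular markers, Acta2 (1.53) and Dcn (0.96) rose and Actg2 fell by 0.97 on the log2 scale. Adjusted over the list alone 4 were higher and 1 lower, and the list of 12 was not called (adjusted p = 0.201). The Leydig marker Insl3 rose (1.55; list adjusted p = 0.923). Cnot8, a deadenylase gene, rose (1.66) and was the called member of the 35 RNA decay genes (list median 0.045, adjusted p = 0.798). Without wild-type library 1 the list pointed down, with a median of -0.126. Camera did not call the meiotic prophase (adjusted p = 0.923), flagellum (0.301), postmeiotic regulator (0.0602) or stress and apoptosis lists (0.212). It did not call the spermatogonia (0.431) and erythroid (0.201) markers either. None of these lists had a member past the test over all genes. The flagellum (adjusted p = 5.87e-07, 17 members lower) and postmeiotic regulator lists (adjusted p = 6.53e-05, 11 members lower) were called lower without wild-type library 1, each with adjusted p = 0.227 with an estimated correlation. The flagellum list had a median of -0.06 and a mean of 0.01, and the Leydig list a median of -0.17 and a mean of 0.10 with the test pointing up.

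Homozygous and heterozygous spermatids were compared next, since only these genotypes have CB libraries. Tex101 (log2 4.24, adjusted p = 0.00224), Angptl2 (3.82) and Nptx2 (2.89) were again among the genes with the largest rise. Lrrc61, encoding a leucine-rich repeat protein, rose from 8.46 ± 1.04 to 75.8 ± 4.33 CPM (log2 3.16, SE 0.164, adjusted p = 0.00512). Gsdmd, the gasdermin D gene, rose by 2.81, and Meox1 and Evpl by 2.67 each. Fam205a2 had 0 counts in heterozygotes too, which makes homozygotes at least 168-fold higher. The long non-coding RNA Malat1 (-1.88), the immune gene Cd5l (-1.75), Myo6 (-1.44) and Adh7 (-1.42) fell. Acrosome (camera adjusted p = 0.000354), Sertoli (0.00147) and flagellum genes (0.0104) were called lower as lists, each with adjusted p above the threshold with an estimated correlation (0.564, 0.478 and 0.564). Adjusted over the list alone, 2 Sertoli markers were lower. By fry, Sertoli markers, immune markers and postmeiotic regulators passed (adjusted p = 0.0246 each), and acrosome (0.175) and flagellum genes (0.321) did not. Without wild-type library 1 chromatoid body (adjusted p = 0.00351), late spermatid (0.033), postmeiotic regulator (0.00656) and RNA decay genes (0.0138) were also called lower and ribosomal proteins higher (0.00516), and with the length trend removed histones were called lower (0.0409; 0.342 with an estimated correlation). The calls without wild-type library 1 did not hold with an estimated correlation (adjusted p = 0.302 for the lower lists and 0.748 for ribosomal proteins). EdgeR called 308 genes (242 higher, 66 lower; 2969 at an unadjusted p under 0.05) and DESeq2 796. The edgeR count was 5608 (2875 higher, 2733 lower) without wild-type library 1, which enters through the shared spread, and 5577 (2887 and 2690) with only the compared libraries. It was 0 without either heterozygous or either homozygous library (1491 and 1485, and 1434 and 1558, at an unadjusted p under 0.05; DESeq2 was not run on these subsets).

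Between heterozygous and wild-type spermatids edgeR called 0 of 17809 genes, with 1296 at an unadjusted p under 0.05, and DESeq2 called 5. The genes of smallest p were Gm20671 (2.04 ± 0.357 CPM in heterozygotes, 0 counts in wild type), the immune gene Cd74 (7.62 ± 0.0658 against 2.81 ± 0.273 CPM) and Gm20862 on chromosome Y (0 counts in heterozygotes, 4.41 ± 2.17 CPM in wild type), all with adjusted p = 0.519. The log2 changes of this comparison rose with transcript length across genes (Spearman rho 0.559), against 0.335 for homozygotes and wild type. As lists, ribosomal protein genes were called lower (median -0.54, camera adjusted p = 8.95e-10, adjusted p = 0.587 with an estimated correlation) and immune markers higher (median 0.72, adjusted p = 0.00107, adjusted p = 0.475 with an estimated correlation). Acrosome genes were called lower (adjusted p = 0.0154) and RNA decay genes (0.0154) and spermatogonia markers (0.0386) higher, each with adjusted p = 0.587 with an estimated correlation. Adjusted over the list alone, 3 immune markers were higher. By fry, immune markers (adjusted p = 0.0145), spermatogonia markers (0.0363) and postmeiotic regulators (0.0497) passed. Ribosomal protein (0.588), acrosome (0.529) and RNA decay genes (0.586) did not. With the length trend removed, the ribosomal protein (median -0.09, adjusted p = 0.155), acrosome (0.04, adjusted p = 0.987) and RNA decay lists (-0.01, adjusted p = 0.987) were not called. Without wild-type library 1 they were not called either (adjusted p = 0.0566, 0.3 and 0.948), nor were spermatogonia markers (0.0566), while chromatoid body (0.00104) and postmeiotic regulator genes (0.00682) were called lower, both with adjusted p = 0.511 with an estimated correlation. The edgeR count was 161 without wild-type library 1 and 7901 without wild-type library 2.

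In CB libraries, Evpl, encoding the cornified envelope protein envoplakin (chromosome 11, from 116220559), rose from 11.7 ± 0.738 CPM in heterozygotes to 55.8 ± 2.41 in homozygotes (log2 2.26, SE 0.113, adjusted p = 2.5e-05, n = 3 each). The magnesium transporter gene Slc41a1 rose from 29.6 ± 1.76 to 96.2 ± 2.20 CPM (log2 1.70, adjusted p = 7.25e-05). Sel1l3 (2.69), Kif26b (2.12), Psd4 (1.88), Tex101 (1.65), Ffar1 (1.47), Pard6g (1.42), Stat6 (1.37) and Angptl2 (1.35) rose as well. Prm1, the gene of protamine 1, which packs sperm chromatin, fell from 214 ± 87.2 to 88.9 ± 2.17 CPM (log2 -1.27, adjusted p = 0.0216). Wbscr25 fell from 311 ± 30.9 to 140 ± 3.79 CPM (log2 -1.16, adjusted p = 0.00183), and Tppp2 fell by 1.04 on the log2 scale. The mitochondrial transcripts mt-Nd2 (-1.96), mt-Rnr1 (-1.25) and mt-Nd4l (-1.10) and the receptor gene Vmn1r43 (-1.25) also fell. Pcdha5 (-1.30), Pcdha4 (-1.21) and Pcdha6 (-1.19) share exons, so their counts are uncertain.

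Late spermatid genes were the list with the smallest p in CB libraries (camera adjusted p = 2.41e-09, adjusted p = 0.15 with an estimated correlation). Of 23 members, 6 fell and none rose, among them Prm1, Tssk6 (-0.73, adjusted p = 0.00666), Odf1 (-0.83) and Spata18 (-0.58). Adjusted over the list alone, 14 were lower and 1 higher. Acrosome genes were lower too (adjusted p = 0.00277, adjusted p = 0.193 with an estimated correlation), with Crisp2 (-0.97) and Spaca1 (-0.49) called of 23 and 8 adjusted over the list alone. Mitochondrially encoded genes had a median of -1.10 (adjusted p = 1.57e-08, adjusted p = 0.377 with an estimated correlation; 3 of 15 called, 7 adjusted over the list alone). Small nuclear and nucleolar RNAs had a median of -0.52 (adjusted p = 6.01e-07, adjusted p = 0.268 with an estimated correlation), with the RNA of RNase MRP, Rmrp, called (-0.75) of 25 and 3 adjusted over the list alone. This list was not called with the length trend removed (median -0.17, adjusted p = 0.079). Sertoli markers (median -0.31, adjusted p = 0.00277) and histones (-0.29, adjusted p = 0.0369) were called lower and Leydig markers higher (0.14, adjusted p = 0.0423) with no member called over all genes, and with adjusted p of 0.637, 0.751 and 0.751 with an estimated correlation. Adjusted over the list alone 1 Sertoli marker was lower, 0 histones passed and 1 Leydig marker was higher. Without heterozygous library 1 the histone median was -0.56 (adjusted p = 1.16e-11; 15 members lower over all genes, 24 adjusted over the list alone), that of Sertoli markers -0.49 (4 lower, 9 adjusted over the list alone), and Leydig markers were not called (adjusted p = 0.762). The histone and Sertoli calls there did not hold with an estimated correlation (adjusted p = 0.274 for both). With the length trend removed the histone median was -0.14 and the list was not called (adjusted p = 0.473). Of the flagellum genes Drc1 rose (0.57) and Odf1 fell, and of the piRNA pathway genes Spocd1 (0.71) and Henmt1 (0.52) rose. Of the ribosomal proteins Rps3 rose (0.76) and Rpl41 fell (-0.67). Cd74 (1.60) and Ccnd2 (0.74) rose among immune and spermatogonia markers. Syce2 (-0.60) fell among meiotic prophase genes and Actg2 (-0.91) among peritubular markers. Chromatoid body, RNA decay, postmeiotic regulator, stress and apoptosis, and erythroid genes had 0 called members and no list call (adjusted p from 0.105 to 0.962). Ribosomal RNA-like reads differed as well: CT010467.1 took 13.0 ± 1.49% of counts in heterozygotes and 6.69 ± 0.183% in homozygotes.

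EdgeR called 332 of 19335 genes in CB libraries, 224 higher and 108 lower, with 2812 at an unadjusted p under 0.05, and DESeq2 called 598. Every left-out library moved the count. It was 2213, 130 and 106 without heterozygous library 1, 2 or 3, and 51, 56 and 75 without homozygous library 1, 2 or 3.

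The homozygous against heterozygous changes of round spermatid and CB libraries, which share no library, were correlated across 16016 genes (Pearson r = 0.421, Spearman rho 0.368, permutation p = 1e-05 for both, the smallest that 100000 permutations can give). Of the genes tested in both, 228 were higher in spermatids and 219 in CB libraries, and 69 were shared, against 3.12 for independent lists. Shared genes included Tex101, Lrrc61, Evpl, Sel1l3, Slc41a1, Kif26b and Stau1, which encodes a double-stranded RNA-binding protein (1.56 and 0.78 on the log2 scale). Among the lower genes 8 were shared of 66 and 95, against 0.391 for independent lists, among them Etfb (-1.79 and -0.90), Dact3 (-1.55 and -0.89) and Plcb4 (-1.40 and -1.04). No gene was called in opposite directions. The shared higher count was 113 without heterozygous CB library 1, 39 and 30 without heterozygous CB library 2 or 3, and 20, 19 and 22 without homozygous CB library 1, 2 or 3. The shared lower count was 25, 4, 3, 2, 2 and 2 in the same order. Leaving out any 1 of the 4 compared spermatid libraries, edgeR called 0 spermatid genes, so none were shared, while Pearson r stayed between 0.342 and 0.408 over all 10 left-out libraries.

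Wild-type small RNAs give the background for the genotype comparisons. Pachytene clusters, which are active from mid-meiosis, took 80.5 ± 0.159% of cluster reads in spermatocytes and 90.7 ± 0.70% in spermatids, prepachytene clusters 14.1 ± 0.162% and 5.47 ± 0.583%, and hybrid clusters 5.37 ± 0.003% and 3.82 ± 0.117% (SD, n = 2 each). The median log2 change from spermatocytes to spermatids was 1.49 higher for pachytene than for prepachytene clusters (permutation p = 1e-05, the smallest possible; adjusted p = 1.14e-05). The intergenic pachytene cluster on mm10 chromosome 4 at 57360190 to 57364266 rose from 0.222 ± 0.000531% to 0.529 ± 0.0299%, 1.48 on the log2 scale above the median cluster (adjusted p = 2.2e-09). The prepachytene cluster pi-Shank3.1 fell from 0.0966 to 0.0274% (-1.59 relative to the median cluster). Of 214 clusters 185 were called, 104 higher and 81 lower, and 60 higher and 115 lower without TMM.

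**Figure D2:**
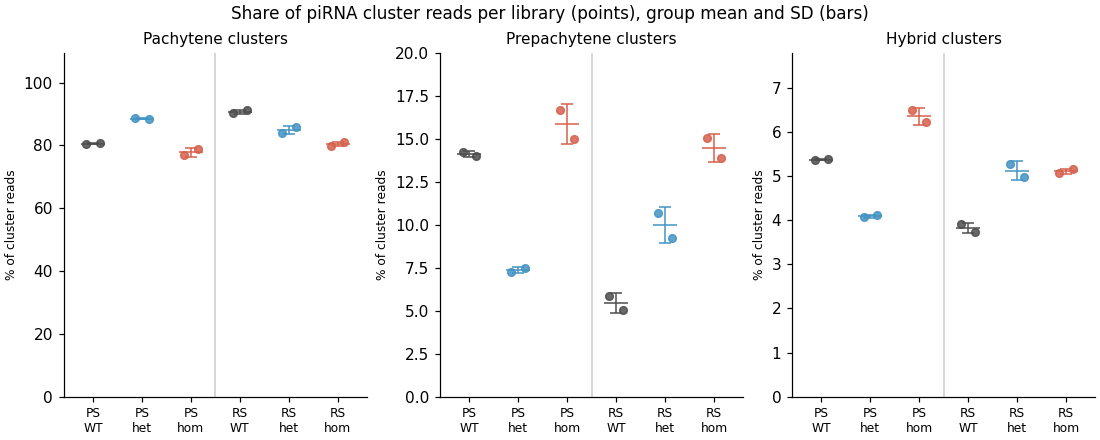
Percent of cluster reads on pachytene, prepachytene and hybrid clusters in each small RNA library of pachytene spermatocytes (PS) and round spermatids (RS), with group mean and SD (points and bars, each panel with its own axis from 0). In libraries labelled spermatids the prepachytene share is 5.47% in wild type, 9.98% in heterozygotes and 14.5% in homozygotes on average. For the libraries labelled heterozygous, exchanged cell type labels could not be told apart from an effect of genotype.

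In homozygous spermatids pachytene clusters took 80.4 ± 0.742% of cluster reads, below the 90.7 ± 0.70% of wild type, and prepachytene clusters 14.5 ± 0.803%. These shares lay near the 80.5% and 14.1% of wild-type spermatocytes. The mean r of homozygous spermatids was 0.966 with wild-type spermatocytes and 0.93 with wild-type spermatids. Of their clusters 33.5% lay outside the range of both wild-type cell types. How much of the shift a different mix of cell types gives was not tested. The class medians moved apart by -1.41 on the log2 scale (pachytene minus prepachytene, permutation p = 1e-05, the smallest possible, adjusted p = 1.14e-05). Genic clusters rose by 1.30 relative to intergenic ones (same p). That is largely the same contrast, since 93 of 100 pachytene clusters were intergenic and 81 of 84 prepachytene clusters were genic. The prepachytene cluster pi-Ppp1r15b.1 (chromosome 1, 133131137 to 133139782) carries the name of a phosphatase regulator gene of the stress response. It rose from 0.0166 ± 0.00201 to 0.152 ± 0.0502% of cluster reads, 2.86 above the median cluster (adjusted p = 2.36e-07). The prepachytene cluster pi-Map3k9.1 rose from 0.0572 ± 0.00422 to 0.289 ± 0.0185%, 2.01 above the median cluster (adjusted p = 6.59e-09). The pachytene clusters on chromosome 13 from 21503620 (-1.48) and on chromosome 4 from 123894130 (-1.42) fell relative to the median cluster. Of the clusters with most wild-type reads, that on chromosome 9 from 67691251 fell from 3.98 ± 0.0554 to 2.56 ± 0.0653%. Its log2 change was -0.97 relative to the median cluster and -1.095 as fitted (adjusted p = 4.86e-10 for the fitted change). The genic cluster pi-Mafg.1 was not listed for either homozygous spermatid library, where the lowest listed counts were 86 and 68 reads (15 in the library with the lowest), and had 211 to 410 reads in the other 10 small RNA libraries. EdgeR called 186 clusters, 85 higher and 101 lower (115 and 61 without TMM). The homozygous spermatid libraries differed more from each other than those of any other small RNA group. The SD of their log2 differences was 0.479, against 0.0793 to 0.136 in the other groups. The shared estimate of spread may therefore be too small for comparisons with these libraries, and their p-values too low.

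In homozygous spermatocytes the class medians differed by -0.16 (permutation p = 0.0007, adjusted p = 0.0007; 95% bootstrap interval -0.30 to -0.02 over clusters drawn within each class). Without homozygous spermatocyte library 1 the difference was -0.10 and did not pass the test (permutation p = 0.153), so it rests on that library. Pachytene clusters took 77.8 ± 1.36% and prepachytene clusters 15.9 ± 1.17% of cluster reads in homozygous spermatocytes. Single pachytene clusters moved further. The intergenic cluster on chromosome 7 at 73105311 to 73126555 fell from 1.15 ± 0.00845 to 0.393 ± 0.00929% (-1.72 relative to the median cluster, adjusted p = 1.67e-09). The cluster on chromosome 15 at 74636387 to 74648452 fell from 1.93 ± 0.0116 to 0.654 ± 0.00656% (-1.73, adjusted p = 5.95e-10), and that on chromosome 10 at 18796805 to 18831930 from 0.657 ± 0.022 to 0.184 ± 0.00466% (adjusted p = 1.87e-08). The pachytene clusters on chromosome 8 from 110117665 (1.38) and on chromosome 4 from 57360190 (1.37) and the hybrid cluster pi-Exoc8.1 (1.88) rose relative to the median cluster. EdgeR called 146 clusters, 118 higher and 28 lower. That split depended on the scaling, with 35 higher and 61 lower under RLE factors and 73 and 33 without TMM, since the median of all clusters stood at 0.30, -0.03 and 0.17 on the log2 scale. Without homozygous spermatocyte library 1, 80 clusters were called.

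**Figure D3:**
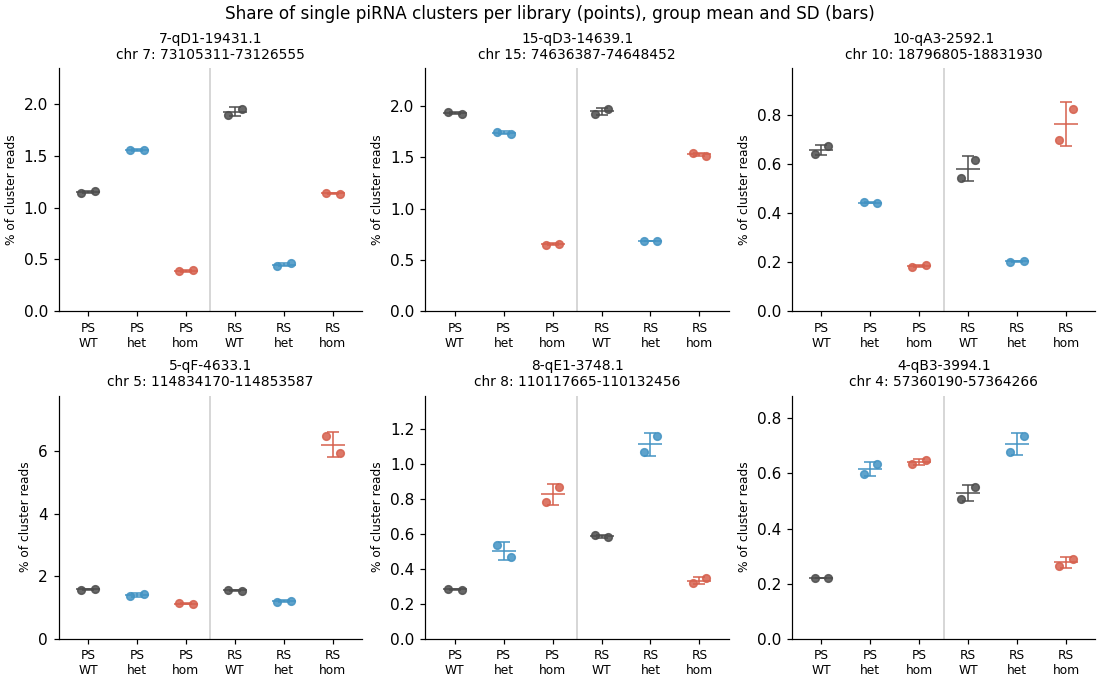
Percent of cluster reads on 6 pachytene clusters in each small RNA library of pachytene spermatocytes (PS) and round spermatids (RS), with group mean and SD (points and bars). The share of the chromosome 7 cluster from 73105311 is 0.393% in homozygous spermatocytes and 0.451% in heterozygous spermatids, and that of the chromosome 5 cluster from 114834170 reaches 6.21% in homozygous spermatids.

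The effect of the homozygous knock-in differed between the cell types for 171 of 214 clusters, 64 higher and 107 lower in spermatids (101 and 74 under RLE factors, 110 and 63 without TMM, where the median of all clusters moved from -0.28 to 0.15 and 0.31). The cluster on chromosome 5 at 114834170 to 114853587 stood at 6.21 ± 0.392% in homozygous and 1.55 ± 0.0115% in wild-type spermatids, against 1.13 ± 0.0142% and 1.58 ± 0.00497% in spermatocytes. The class medians of this difference lay -1.30 apart (pachytene minus prepachytene, permutation p = 1e-05, the smallest possible; adjusted p = 1.14e-05).

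The small RNA libraries labelled heterozygous shifted in opposite directions in the 2 cell types. In those labelled spermatocytes, pachytene clusters took 88.5 ± 0.209% and prepachytene clusters 7.39 ± 0.179%, and the class medians moved by 0.98 against wild type. In those labelled spermatids the shares were 84.9 ± 1.25% and 9.98 ± 1.04%, and the medians moved by -0.74. The permutation p was 1e-05 for both, the smallest possible (adjusted p = 1.14e-05). In the libraries labelled heterozygous spermatids the chromosome 7 cluster from 73105311 fell from 1.93 ± 0.0406 to 0.451 ± 0.0155% (-2.53 relative to the median cluster, adjusted p = 1.62e-11). The chromosome 15 cluster from 74636387 fell from 1.95 ± 0.0337 to 0.687 ± 0.00131% (-1.94, adjusted p = 2.28e-11). In the libraries labelled heterozygous spermatocytes the chromosome 7 cluster stood at 1.56% against 1.15 ± 0.00845% in wild type. The prepachytene clusters pi-Shank3.1 and pi-Rad54l2.1 fell in the spermatocyte libraries (-1.10 and -0.96), and the hybrid cluster pi-Exoc8.1 rose in the spermatid libraries (1.24). EdgeR called 172 clusters in spermatocytes (97 higher, 75 lower; 51 and 112 without TMM) and 165 in spermatids (93 and 72; 133 and 40 without TMM).

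Against libraries labelled heterozygous, homozygous spermatocytes had lower pachytene than prepachytene medians by -1.13, and homozygous spermatids by -0.67. The permutation p was 1e-05 for each, the smallest possible (adjusted p = 1.14e-05). Exchanged cell type labels of the heterozygous libraries could not be told apart from genotype, so these comparisons may mix cell types. In spermatocytes the pachytene clusters on chromosome 4 from 123894130 (-2.96), chromosome 7 from 73105311 (-2.61) and chromosome 15 from 78653228 (-2.02) fell relative to the median cluster, and pi-Shank3.1 (0.74) and pi-March08.1 (0.71) rose. In spermatids the chromosome 5 cluster from 114834170 (2.19) and pi-Cdc42ep3.1 (2.16) rose, and the chromosome 8 cluster from 110117665 (-1.93) and the chromosome 17 cluster from 49112270 (-1.76) fell. EdgeR called 180 clusters in spermatocytes (111 higher, 69 lower; 87 and 85 under RLE factors, 129 and 43 without TMM) and 155 in spermatids (75 and 80; 88 and 72 without TMM).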

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

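Which effects differ between kinds of library, and the calls without wild-type library 1, were tested as planned; the other tests of explanations, and the fits without transcript length trends, were chosen only after the results had been seen. The outcome that each explanation predicts was also set down after them, except for the length tests, where it was set down before those tests were run.

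The effect of the homozygous against the heterozygous knock-in differed between CB and round spermatid libraries for 269 of 21706 genes, 159 higher and 110 lower in CB libraries (187 genes, 77 and 110, under RLE factors). Values are CB minus round spermatid log2 changes, and a difference between genotype effects drew attention to each. Positive were the prostaglandin D synthase gene Hpgds (3.10), the cyclin gene Ccnd2 (2.67), Ccdc177 (2.12), Malat1 (1.85), Ube2v1 (1.65), ENSMUSG00000118603 (1.59), Ddx4 (1.59), C1qtnf3 (1.45) and Shisa7 (1.40). Negative were Tex101 (-2.53), Angptl2 (-2.42), Arhgef15 (-2.28), Etl4 (-2.23), Stambp (-2.22), Sh2b2 (-2.09), Prkx (-2.09), the DEAD-box helicase gene Ddx28 (-2.03), Lrrc61 (-1.88) and Ttyh2 (-1.86). Tex101, Angptl2 and Lrrc61 rose in both kinds of library and by less in CB libraries. For none of these genes can a difference in CB RNA itself be told apart from kit, input or the cells used. The count was 2135 without heterozygous CB library 1 and 175 without library 2, and 77, 94 and 121 without homozygous CB library 1, 2 or 3. It was 31 and 41 without either heterozygous and 38 and 61 without either homozygous round spermatid library.

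The effect of the homozygous knock-in on clusters differed between spermatids and spermatocytes for 171 of 214 clusters. As fitted log2 differences, with a median of -0.28 over all clusters, the largest positive ones among named clusters with reads in every group were pi-Cdc42ep3.1 (2.65), pi-Ppp1r15b.1 (2.41), pi-Tfcp2l1.1 (2.03), pi-Zdhhc23.1 (2.02) and the chromosome 5 cluster from 114834170 (1.90). The largest negative ones among these were pi-Lsmd1.1 (-3.81; not listed for homozygous spermatid library 2 and set to 0 there) and the clusters on chromosome 10 from 20310505 (-3.19), chromosome 4 from 57360190 (-3.06) and chromosome 8 from 110117665 (-2.95). Clusters not listed for either homozygous spermatid library, pi-Mafg.1 among them, were left out here, since their fitted values depend on the prior count. Homozygous spermatid library 1 carried much of pi-Zdhhc23.1 (0.84 without it, 2.66 without library 2) and of pi-Tfcp2l1.1 (1.40 without library 1), and pi-Lsmd1.1 gave -2.88 without library 2.

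The genes called in homozygous against wild-type round spermatids, Tex101 and Angptl2 among them, were weighed against library artifacts. Without wild-type library 1, 100% of the 510 genes were called in the same direction, so their directions did not depend on it. Leaving it out also lowered the shared spread and left 1 wild-type library, which makes calls easier to keep. The kept calls therefore do not decide whether that library is a source of the calls. With the length trend removed, the median log2 of the genes called higher was 1.445 (before, 1.504; SD 1.05), so length bias may account for little of it. A lower share of spermatids with a like gain of every other cell type would raise all their markers. Sertoli markers had a median of -0.842 and immune markers of 1.052, which argues against such a like gain. A gain of some cell types alone need not raise them all. Spermatocytes and later spermatids were not among the 6 lists, so these values do not decide on a lower share as such. The medians of the 6 lists of other cells spanned 1.89, more than with members permuted over these lists (permutation p = 0.0216 for the span), though members are not independent and neither list call held with an estimated correlation. An effect of the knock-in on these transcripts, a change in immune cells alone, wild-type library 1 and a lower share of spermatids stay open. So does the lack of calls without either homozygous library.

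Of the small RNA libraries labelled heterozygous, those of spermatocytes resembled wild-type spermatids. Those of spermatids resembled wild-type spermatids and wild-type spermatocytes alike. Heterozygous spermatocytes had a mean r of 0.995 with wild-type spermatids and 0.972 with wild-type spermatocytes, and 7.08% of their clusters (15 of 212) lay outside the range of both wild-type cell types, as a mix of cell types in which spermatids dominate could give. The same mix is argued against for heterozygous spermatids, with 32.1% outside. An exchange of cell type labels without an effect of genotype would need heterozygous spermatids to match wild-type spermatocytes. Their mean r with these was 0.97, against 0.971 with wild-type spermatids. With an effect of genotype, an exchange would not need such a match. The mean r of heterozygous spermatids was 0.988 with homozygous spermatocytes and 0.944 with homozygous spermatids, as an exchange together with an effect of genotype could give. Exchanged labels therefore cannot be told apart from an effect of genotype. Neither a swap outside these groups nor an effect of the heterozygous knock-in was tested.

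Late spermatid genes, Prm1 among them, were lower in homozygous CB libraries. The camera call of these genes did not hold with an estimated correlation (adjusted p = 0.287 with the length trend removed). Their list median was -0.487 as tested, -0.411 (SD 0.362 across members) with the length trend removed, and -0.389 without heterozygous CB library 1, which argues against either as the whole source of the difference. The ribosomal RNA-like genes took a smaller share of counts in homozygotes than in heterozygotes. Before scaling, this would raise all other genes by 0.109 on the log2 scale (0.073 to 0.131 over 9 pairs of libraries). The tested changes were scaled by TMM, with a median over all genes of -0.005 (0.022 without TMM). Scaling takes out a shift common to all genes, so the 0.109 does not decide on these genes as a source of the fall. A different mix of germ cell stages in the preparations may give it as well as an effect of the knock-in on CB RNA, and no value decides between them. For the 332 genes called in CB libraries, the highest count among the other splits of the 6 libraries was 3, and only 1 of 10 splits, the real one, called as many; 10 splits are too few for a share under 0.05.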

How the results depend on the processing

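The settings with the length trend removed, without ribosomal RNA-like genes, the list and cluster class tests without 1 library, and homozygous against heterozygous spermatids without wild-type library 1 were chosen after the data had been seen; the others were planned. For genes called in homozygous against wild-type spermatids (510), homozygous against heterozygous spermatids (308), CB libraries (332) and the CB minus spermatid difference (269), DESeq2 gave 1287, 796, 598 and 599, and no filter 1692, 912, 882 and 679. With the replicate number as a block they gave 182, 12, 163 and 59; the numbers do not pair the samples. With only the compared groups in the fit the first 2 gave 15 and 5577, and with the length trend removed 2490 and 1753. Heterozygous against wild-type spermatids (0 by edgeR, 1296 at an unadjusted p under 0.05) gave 5 with DESeq2 and 6 without a filter. Spermatocyte clusters of homozygotes against wild type (146) gave 93 with DESeq2 and 96 with RLE. Leaving out 1 library gave 0 to 8488, 0 to 5608, 51 to 2213 and 31 to 2135 genes for the same 4 results, 0 to 7901 for heterozygous against wild-type spermatids, and 80 to 134 spermatocyte clusters; with 1 library left out the pachytene minus prepachytene difference of homozygous spermatocytes was -0.233 to -0.096 and the genic minus intergenic one 0.093 to 0.189, neither past the test without homozygous library 1; a lone sample left in a group was assumed to vary like the other groups. The other cluster counts stayed within 1.5 times under each setting run. Without wild-type library 1 some lists changed direction, with camera adjusted p of 0.0195 for RNA decay and 6.53e-05 for ribosomal proteins in homozygous spermatids, and 0.00104 for chromatoid body proteins and 0.0566 for ribosomal proteins in heterozygous spermatids. It was, with the length trend removed, 0.782 for ribosomal proteins in homozygous spermatids, and 0.987 for both RNA decay and genic-cluster genes in heterozygous spermatids.

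Clusters that changed sign had fitted log2 changes, not relative to the median cluster, from -0.41 to 0.50 as tested. In homozygous spermatocytes that on chromosome 2 from 92541141 gave -0.208 with DESeq2 and with RLE, -0.009 without TMM, -0.153 with the same cell type alone, and -0.037 to 0.123 when 1 library was left out. Without TMM that on chromosome 5 from 113340137 gave -0.109 in heterozygous spermatocytes, 0.049 in homozygous spermatids and -0.04 between wild-type cell types, and that on chromosome 18 from 67029446 gave 0.044 between homozygous and heterozygous spermatocytes. That on chromosome 17 from 27325196 gave, for the spermatid minus spermatocyte difference, 0.291 with DESeq2 and with RLE, and 0.452 without TMM, and -0.182 to 0.369 when 1 library was left out. Between wild-type cell types it gave -0.502 without TMM, and -0.239 to 0.082 when 1 library was left out. Apart from the scaling itself, the cause was not tested. Genes named by the size of a change between groups were chosen for separate groups in these same data, so leaving out a library could hardly reverse them. Of 1723 values of named genes under alternatives, 1234 kept direction and side of the threshold, 477 lost the call, 12 gained it and 0 reversed. Of 1350 values of named clusters 1289 kept both, and of 296 of gene lists 222, with 51 losing the call, 16 gaining it and 7 reversed.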

Other observations

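The test of precursor RNA, the list of genes named in genic clusters and the interval of its correlation were chosen after the data had been seen; the outcome predicted for the precursor test was set down before it was run.

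Genic piRNA clusters are named for the gene whose transcript they overlap. In CB libraries 13 of 105 of these genes rose and none fell, and adjusted over the list alone 25 were higher and 1 lower. The list was called by camera (adjusted p = 6.78e-09) and not with an estimated correlation (adjusted p = 0.217). Without heterozygous CB library 1, 31 rose and 6 fell (camera adjusted p = 8.42e-06, adjusted p = 0.448 with an estimated correlation). Eif4ebp2, encoding a repressor of translation initiation, stood at 143 CPM in homozygotes and 72.0 in heterozygotes (log2 0.99), and Tktl2 (0.77), Bcl2l13 (0.68) and Arhgap20 (0.63) rose too. In round spermatids 7 of 103 rose and 1 fell against wild type, 17 and 2 adjusted over the list alone (camera adjusted p = 3.61e-05, adjusted p = 0.562 with an estimated correlation), and 30 rose and 13 fell without wild-type library 1 (camera adjusted p = 0.0132, adjusted p = 0.366 with an estimated correlation). The heterozygous list median against wild type was 0.28 (camera adjusted p = 0.000315, adjusted p = 0.585 with an estimated correlation), and homozygotes against heterozygotes were not called (median 0.09, adjusted p = 0.112). Without wild-type library 1 heterozygotes against wild type were not called (median 0.06, adjusted p = 0.519), and homozygotes against heterozygotes were (31 higher, 11 lower, adjusted p = 0.0277; 0.434 with an estimated correlation). With the length trend removed the list median went from 0.13 to 0.06 in CB libraries and from 0.33 to 0.10 in round spermatids (camera adjusted p = 0.00043 and 0.0352; 0.498 and 0.24 with an estimated correlation). With it removed, heterozygotes against wild type were not called (median 0.06, adjusted p = 0.987), and homozygotes against heterozygotes were called higher (median 0.16, adjusted p = 0.00482; 0.169 with an estimated correlation). Mgll, the monoglyceride lipase gene, stood at 57.5 CPM in homozygotes against 13.8 in wild type (log2 2.06), and Cdc42ep3 at 156.7 against 60.03 (1.38), while Ccdc117 fell (-1.51).

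A candidate explanation is that precursors accumulate where fewer piRNAs are made from them, which predicts a negative relation between the RNA and small RNA changes of the same locus. Across 103 genic clusters of round spermatids (homozygous against wild type) Spearman's rho was 0.151 (permutation p = 0.128, 95% bootstrap interval -0.061 to 0.354 over 10000 draws) and Pearson's r was 0.049 (permutation p = 0.605). As measured, these loci showed no negative relation. The interval covers the draw of loci alone and leaves out the spread between libraries, which can weaken a correlation. Small RNA values are relative to cluster reads, so a fall common to all clusters would not show. The test therefore does not decide on this explanation. The RNA and small RNA changes come from separate libraries, and loci are not independent replicates.

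In CB libraries the protein-coding gene Lars2, grouped here as ribosomal RNA-like, took 1.01 ± 0.228% of counts in heterozygotes and 0.544 ± 0.014% in homozygotes (n = 3 each). Mitochondrially encoded genes took 0.497 ± 0.131% and 0.279 ± 0.0786% (n = 3 each).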
